A study of Homo sapiens with 4 samples.

How the data were processed

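RNA of HCT116 cells transfected with control siRNA (2 samples) or TET1 siRNA (2 samples) was measured on 1 Affymetrix GeneChip array each. Per the labels' protocols, siRNA was introduced with a lipid reagent, cDNA was primed with oligo(dT), and biotin-labelled cRNA was hybridised, so signals come mainly from the 3' ends of polyadenylated transcripts. The deposited values are an intensity per probe set on a linear scale. In the deposited table each array has the same mean after trimming 2% of probe sets at either end (100.01), so the authors' values were scaled array by array. The software, background correction and scaling target are not given in the sources used here, and detection calls were not used here. A global scaling hides any change in total mRNA, and differences of dim probe sets depend on the unstated background step.

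Samples were grouped by the siRNA named in their labels. The values were used as deposited, as log2(signal + 16). Of 54675 probe sets, 62 control probe sets were left out. The platform annotation gave 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721, and no gene was named from a probe set with several. Gene identifiers of 41037 probe sets matched the RefSeq table used for current symbols (assembly GRCh38.p14, names only). A gene was represented by its probe set of highest mean signal, which gave 19775 genes, and 12389 whose mean log2 value was above the median of all non-control probe sets (4.86, a signal of 13.1) were tested. Log2 differences are on the log2(signal + 16) scale, which understates the change of dim genes.

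The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of variance on signal), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit leaves 2 residual degrees of freedom, to which the prior adds 9.38. An exact permutation test of 2 against 2 arrays cannot give a p below 0.33, so every p rests on this model. Lists of genes, 37 in number, and 6 lists of cell type markers were fixed before the data were examined, and those with 5 or more measured members were tested with camera (preset inter-gene correlation 0.01), as 2 separate families. The result of 1 of the lists is not reported here; it stays in the counts of lists and in the adjustment. Of 1104 list members written, 1090 matched a current symbol, directly or through a synonym of 1 gene, and 968 of those had a probe set. The matching of older symbols was corrected once after the list results had been seen, because some symbols had gone to another gene with the same synonym; the lists themselves did not change. Camera compares a list with all other genes; fry asks whether a list's genes move one way on balance.

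The rule for named genes was fixed before the data were examined. It takes TET1, the 15 largest rises and 15 largest falls among genes past the threshold with non-overlapping groups, up to 4 members of each list (those past the threshold by size of change, then by p), and genes whose probe sets passed in opposite directions. Genes named for any other reason are said to have been chosen after their values were seen. Alternatives fixed in the same way were quantile normalization, median centring, pseudocounts of 1 and 64, eBayes without trend or without moderation, the replicate number as a block, leaving out each array, other filters on dim probe sets, other choices of probe set, other thresholds, and 3 other list tests (an estimated inter-gene correlation, fry, and ranks). In simulated data 12389 genes varied independently, with variances drawn from limma's fitted prior, and 50 genes were changed at each size. Limma recovered 46% of genes changed by 0.5 on the log2 scale, 82% of those changed by 1 and 98% of those changed by 2. It recovered 74% of those changed by -1, with 3 false calls among 153. Camera called 2 of 2 shifted lists and 0 of 35 unshifted ones. Genes that vary together were not simulated, so this is no check on false calls of real lists. Figures were drawn with matplotlib 3.10.9.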

Results

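The data are expression microarrays of HCT116, an established human colorectal cancer cell line, transfected with a control siRNA (2 arrays) or with an siRNA against TET1 (2 arrays). TET1 encodes a dioxygenase that oxidises methylated cytosine in DNA, and the series asked which genes depend on it in colorectal cancer cells. The series' design text calls the samples biological duplicates. Each array gave 1 signal for each of 54675 probe sets, on a linear scale of arbitrary units that had been scaled to the same trimmed mean on every array (100.01). Median signals were 14.3 and 15.5 on the control siRNA arrays and 13.9 and 14.4 on the TET1 siRNA arrays. Across the genes tested, Pearson's r of the log2 values was 0.9899 and 0.991 within the groups and 0.9757 to 0.9775 between them; genes are not independent replicates. The number of arrays limits the precision of every value below.

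The TET1 transcript was lower on both TET1 siRNA arrays. The brighter of the TET1 probe sets gave a signal of 58.85 ± 1.06 (SD, n = 2) with control siRNA and 14.8 ± 0.283 (SD, n = 2) with TET1 siRNA, which left 25.1% of the control signal. The single values were 58.1 and 59.6 against 14.6 and 15. On the log2(signal + 16) scale it fell by 1.28 (SE 0.20, limma adjusted p = 9.28e-04). The remaining signal lay near the median of all probe sets (percentile 51.7), where background is a large part of a signal, so the remaining transcript can be lower than this ratio. The dimmer probe set gave 26.85 ± 12.2 and 7.45 ± 2.05 (SD, n = 2 each) and did not pass when each probe set was tested by itself (log2 difference -0.84, limma adjusted p = 0.0509). The 2 paralogues did not pass: TET2 had a log2 difference of 0.12 (adjusted p = 0.596) and TET3 of -0.27 (adjusted p = 0.149), both named after their values were seen.

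**Figure D1:**
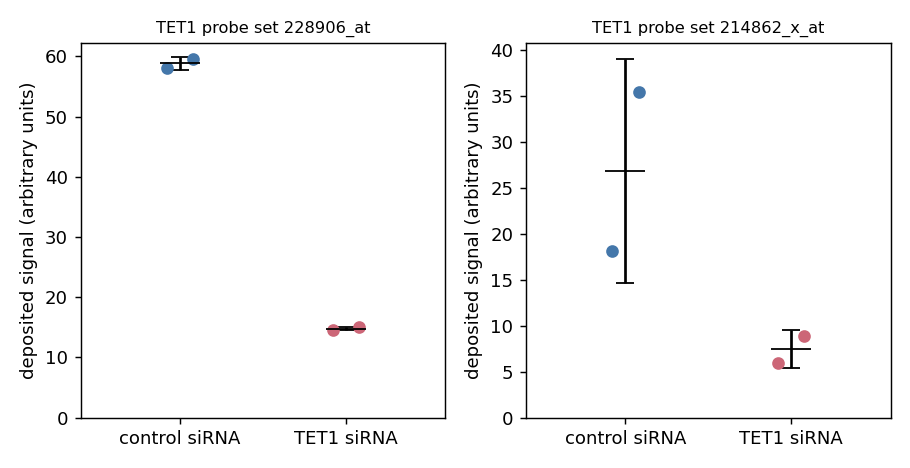
Deposited signal (arbitrary units, linear axis from 0) of the TET1 probe sets on each array. Points are single arrays, horizontal marks are group means and bars are 1 SD (n = 2); the probe set on the left went from 58.85 to 14.8.

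Of 12389 genes tested, 1393 were higher and 1313 lower after TET1 siRNA at adjusted p below 0.05 (51.5% higher). With each array centred on its median they were 1450 and 1008 (59.0% higher), while falls outnumbered rises with the mean of all probe sets of a gene (46.4% higher) and without _x_at and _s_at probe sets (49.3% higher). Most differences were small: 1749 of the 2706 were under 1.5-fold, and 56 rises and 127 falls reached 2-fold. CCN2 (connective tissue growth factor) rose most, from a signal of 17.55 ± 1.91 to 314 ± 45.7 (SD, n = 2), a log2 difference of 3.29 (SE 0.16, adjusted p = 4.25e-07). CCN1, a related secreted matricellular protein, rose by 2.27 (SE 0.15, adjusted p = 2.92e-06). AADACP1, a pseudogene and so open to signal from its parent gene, rose by 2.32. Other large rises were those of CLIP4 (1.72), the collagen gene COL12A1 (1.65), AMOTL2 (1.62), SYTL3 (1.58), SUN3 (1.56), ZNF367 (1.51), ESAM (1.45), CRIM1 (1.44), MIGA1 (1.42), SAMD9 (1.42), TMEM139 (1.40) and CASTOR2 (1.36).

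On the log2(signal + 16) scale BZW2 fell most, from 1719 ± 28.6 to 356.9 ± 7 (SD, n = 2), a log2 difference of -2.22 (SE 0.075, adjusted p = 4.09e-08). HMGA2, an architectural chromatin protein, went from 2888 ± 47.0 to 769.7 ± 0.283 (SD, n = 2; log2 difference -1.89, SE 0.067, adjusted p = 4.09e-08). The lysosomal peptidase gene TPP1 had a log2 difference of -1.91, the methyltransferase gene CARNMT1 of -2.05 (by plain signals its fall was 4.90-fold, against 4.82-fold for BZW2), MTPN of -1.87 and the pseudogene ZNF204P of -1.84. The other large falls were ANTXR1 (-1.72), ARHGAP19 (-1.58), NTPCR (-1.58), the proteasome subunit gene PSMB7 (-1.58), KLC3 (-1.53), FKBP9 (-1.48), RAI14 (-1.47), GPAM (-1.47) and PKP4 (-1.46). ANTXR1 passed in 1 of its 4 probe sets above the filter, each tested by itself. Of the 30 largest rises and falls, 27 still passed with the mean of all probe sets of a gene. In 7309 genes (59.0%) both arrays of one group lay above both of the other, against 33.3% by chance. The counts rest on limma's sharing of variance between genes: without it no gene passed in either direction (2671 at unadjusted p below 0.05), and without the trend of variance on signal 437 were higher and 535 lower. Without TET1 siRNA replicate 1, 813 were higher and 887 lower, and without TET1 siRNA replicate 2, 835 were higher and 879 lower. The labels give 1 TET1 siRNA group, so effects of TET1 loss and of the siRNA itself were not separated by this design.

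**Figure D2:**
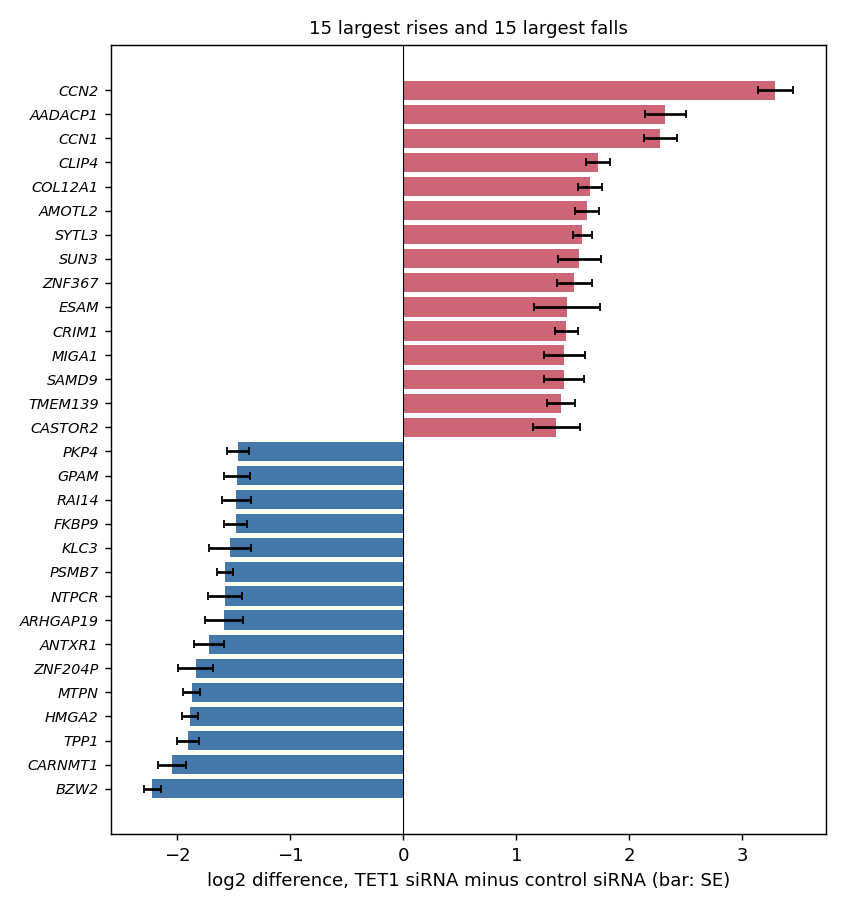
Log2 difference (TET1 siRNA minus control siRNA) of the 15 genes with the largest rise and the 15 with the largest fall. Bars start at 0 and error bars are standard errors from limma (n = 2 arrays per group); the range runs from CCN2 at 3.29 to BZW2 at -2.22.

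Genes of G2/M and mitosis were lower as a group. Of 48 measured members, 36 fell, none rose and 12 did not pass (adjusted over the list alone, 38 fell and 2 rose), with a median log2 difference of -0.51. KIF20A, a kinesin of cytokinesis, went from 515.6 ± 10.5 to 231.7 ± 13.4 (SD, n = 2; log2 difference -1.10). BIRC5 (survivin) fell by 0.94, DEPDC1 by 0.89 and KIF20B by 0.84. CDK1 (-0.61) and the cyclin gene CCNA2 (-0.82) also fell, while the cyclin gene CCNB1 had a log2 difference of -0.01 (adjusted p = 0.937) by its brighter probe set and of -0.51 (limma adjusted p = 0.00823) by the other, tested by itself. These 3 were named after their values were seen. Genes of S phase and DNA replication were lower by less: of 40 measured, 13 fell and 1 rose (15 and 2 adjusted over the list alone). The median was -0.26, and it was -0.18 without TET1 siRNA replicate 1 and -0.32 without TET1 siRNA replicate 2. GINS1 had a log2 difference of -1.25, the clamp loader gene RFC2 of -0.84, the helicase subunit gene MCM7 of -0.67 and GINS2 of -0.56 (0.014, adjusted p = 0.979, without _x_at and _s_at probe sets). The GINS2 value of 0.014 came from a dim probe set (mean signal 21.85 with control siRNA and 23.25 with TET1 siRNA). The probe set that fell read 266.55 and 174.6. The member that rose, named after its value was seen, was the sliding clamp gene PCNA (0.24). Against all other genes, camera gave adjusted p = 4.94e-18 for G2/M and mitosis and 8.22e-05 for S phase. With an estimated correlation, where camera rests on 2 residual degrees of freedom, the adjusted p was 0.524 and 0.63. The estimated correlation was 0.138 and 0.373, above the preset 0.01, so correlation and the few degrees of freedom were not told apart. Fry gave adjusted p = 0.133 for S phase.

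Targets of YAP, a transcriptional coactivator, were higher. Of 21 measured, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 difference of 0.53. CCN2, CCN1, AMOTL2 and CRIM1, given above, led the list. The member that fell was TEAD1 (-0.75, named after its value was seen), which encodes a DNA-binding partner of YAP. TEAD1 passed in 1 of its 3 probe sets above the filter, each tested by itself. Of 16 replication-dependent histone genes on the array 7 lay above the filter, of which 4 rose and none fell (4 and 0 adjusted over the list alone), with a median of 0.98: H2BC9 (1.10), H2BC12 (1.01), H2BC5 (0.99) and H2AC25 (0.98). Histone genes are near-identical copies, and a poly(A)-primed assay reads few of their transcripts, so the values of single histone genes are uncertain. Camera gave adjusted p = 1.18e-06 for YAP targets and 0.00308 for histones, and with an estimated correlation the adjusted p was 0.564 for each. The histone median was 0.55 with the mean of all probe sets of a gene and 0.59 with a pseudocount of 64. The histone call also ended with no filter on dim probe sets (median 0.13, adjusted p = 0.0867) and with fry (adjusted p = 0.0935). With an upper-quartile filter or without _x_at and _s_at probe sets, 4 and 3 histone genes were left, too few to test.

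Genes of oxidative phosphorylation were slightly higher: of 45 measured, 15 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 difference of 0.14. NDUFS3 rose by 0.43, NDUFB5 by 0.41, COX5B by 0.40 and NDUFS1 by 0.38, all encoding respiratory chain subunits; the member that fell was NDUFC1 (-0.23, named after its value was seen). Of 35 measured genes of autophagy and lysosome, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.23. The autophagy receptor gene SQSTM1 rose by 0.81, LAMP2 by 0.73 and ATG14 by 0.71, while CTSA (cathepsin A) had a log2 difference of -0.97. SQSTM1 and LAMP2 each have 1 other probe set that passed in the opposite direction, and without _x_at and _s_at probe sets SQSTM1 was at -0.73 (adjusted p = 0.0459). Of 23 measured targets of NRF2, a regulator of oxidative stress genes, 9 rose and none fell (10 and 1 adjusted over the list alone), with a median of 0.19 (0.29 without control siRNA replicate 1). GCLM rose from 428.9 ± 43.3 to 868.5 ± 19.9 (SD, n = 2; log2 difference 0.99), SLC7A11 by 0.77, HMOX1 by 0.76 and TXNRD1 by 0.55. Hypoxia response genes were lower: of 27 measured, 8 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.15 (-0.24 without TET1 siRNA replicate 1). BNIP3L had a log2 difference of -1.24, PDK1 of -0.60 and PFKFB4 of -0.48, and the member that rose was ANGPTL4 (0.95). Camera's adjusted p was 1.63e-04, 2.20e-04, 0.00602 and 0.00672 for the 4 lists in this order, and with an estimated correlation the adjusted p was 0.506, 0.506, 0.525 and 0.564. Without _x_at and _s_at probe sets, autophagy and lysosome (median 0.20, adjusted p = 0.0999) and NRF2 targets (median 0.12, adjusted p = 0.0672) no longer passed, and fry gave adjusted p = 0.0597 for hypoxia.

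**Figure D3:**
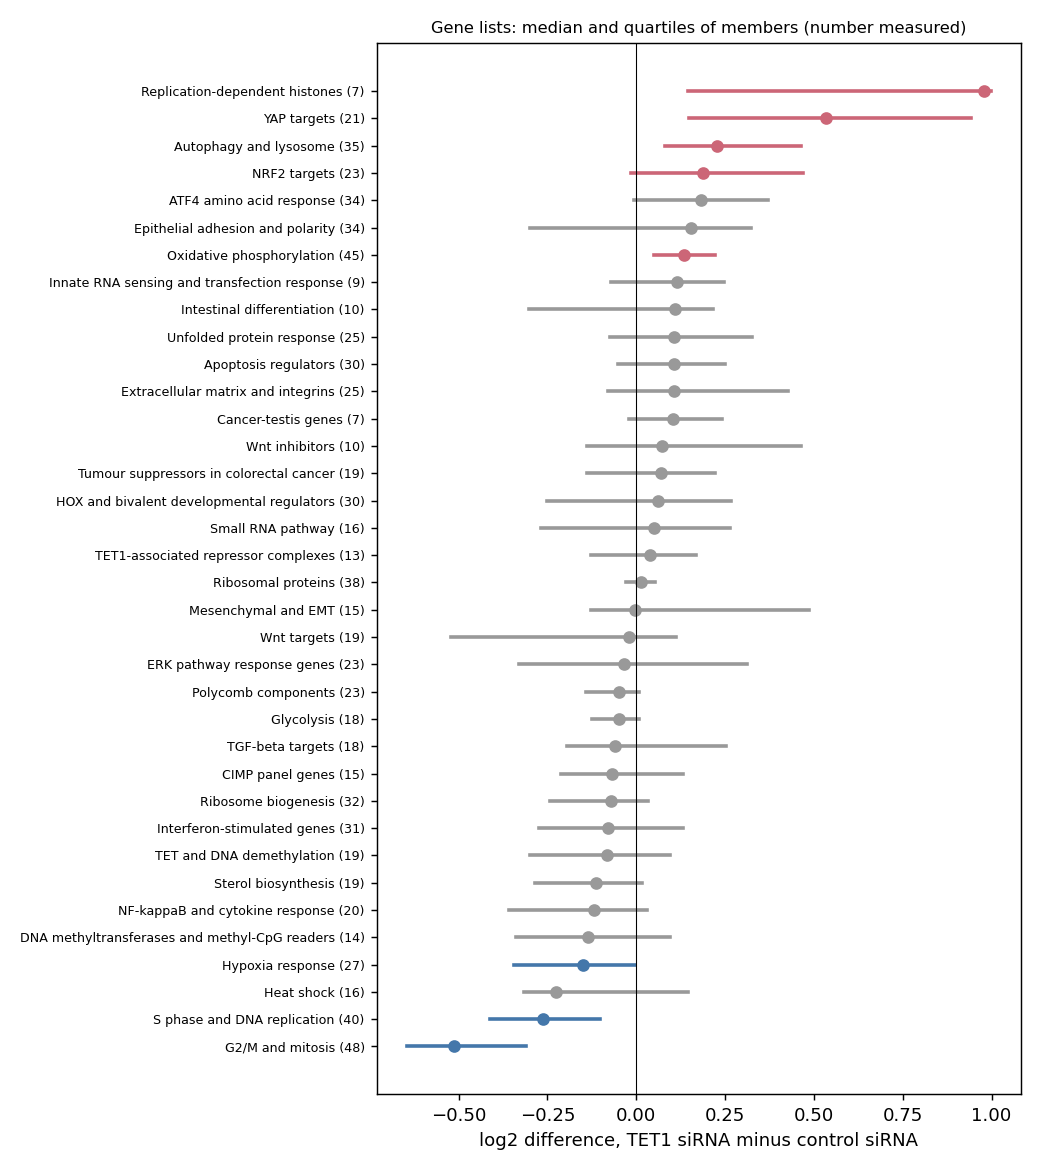
Median (point) and quartiles (line) of the log2 difference, TET1 siRNA minus control siRNA, of the members of each gene list reported, with the number of members measured in brackets. Red lists were higher and blue lists lower at camera adjusted p below 0.05, and grey lists did not pass. No list passes with an estimated correlation, a test that rests on 2 residual degrees of freedom.

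The other 28 lists did not pass (camera adjusted p from 0.0586 to 0.985), but 3 of them passed in some of 17 alternatives. The ATF4 amino acid response passed as higher in 4 (adjusted p 0.0331 to 0.564 over the alternatives): with median centring, with the replicate block, without control siRNA replicate 2 (adjusted p = 0.0461) and with no filter on dim probe sets. TET proteins and DNA demethylation, a list that holds TET1 itself, passed as lower in 2, with no filter and with fry (0.0387 to 0.698). DNA methyltransferases and methyl-CpG readers passed as lower in 1, with the mean of all probe sets (0.0355 to 0.944). Adjusted over the list alone, 16 of the 28 had the same counts, and the counts of any other moved by at most 4 genes. In the list of TET proteins and DNA demethylation, 5 of 19 measured members fell and none rose: TET1, the glycosylase gene NEIL3 (-0.68), APOBEC3B (-0.53), CXXC5 (-0.52) and TDG (-0.33, named after its value was seen). Among DNA methyltransferases and methyl-CpG readers 4 of 14 fell and 1 rose: UHRF1, which recruits DNMT1 to DNA, fell by 0.66, HELLS by 0.52 and the maintenance methyltransferase gene DNMT1 by 0.36, while MBD1 rose by 0.56. Of 23 Polycomb components 3 rose and 5 fell, among them PCGF3 (-1.14), RBBP4 (-0.65) and the histone methyltransferase gene EZH2 (-0.65). PCGF3 passed in 1 of its 5 probe sets above the filter, each tested by itself. Of 13 members of TET1-associated repressor complexes 1 rose (SAP18, 0.32) and 2 fell (ING1, -0.58, and SAP130, -0.34). Of 15 genes of CIMP panels, which mark tumours with widespread promoter methylation, 2 rose and 2 fell: THBS1 (1.35), VIM (0.45), CDKN2A (-0.55) and RASSF2 (-0.48). Of 30 HOX and bivalent developmental regulators only MEIS2 passed (-0.52), and no cancer-testis gene of 7 measured did.

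Of 19 Wnt targets 3 rose and 6 fell, with BMP4 (-1.28) and ETS2 (-0.93) among the falls, and of 10 Wnt inhibitors 2 rose, KREMEN2 (0.64) and DKK1 (0.44). In the list of epithelial adhesion and polarity 9 of 34 rose and 6 fell, including CDH1, the E-cadherin gene, from 992 ± 94.7 to 434.4 ± 57.1 (SD, n = 2; log2 difference -1.16). Among 15 mesenchymal genes 4 rose, SNAI2 by 0.83 and AXL by 0.82, and 2 fell, with FN1 (fibronectin) at -1.28. Counts of rises and falls were 7 and 5 of 25 for extracellular matrix and integrins, 3 and 2 of 18 for TGF-beta targets, 6 and 8 of 23 for ERK pathway response genes, and 0 and 2 of 10 for intestinal differentiation. They were 9 and 3 of 34 for the ATF4 amino acid response, 8 and 4 of 25 for the unfolded protein response, 3 and 6 of 16 for heat shock, and 8 and 3 of 30 for apoptosis regulators. They were 4 and 4 of 31 for interferon-stimulated genes, 2 and 0 of 9 for innate RNA sensing and transfection response, and 1 and 3 of 20 for the NF-kappaB and cytokine response. They were 1 and 5 of 32 for ribosome biogenesis, 1 and 2 of 19 for sterol biosynthesis, 0 and 2 of 18 for glycolysis, 3 and 3 of 16 for the small RNA pathway, and 3 and 4 of 19 for tumour suppressors in colorectal cancer. No ribosomal protein gene passed, of 38 measured. The median, mean and test of a list differed in sign for 6 lists: mesenchymal and EMT, intestinal differentiation, TET1-associated repressor complexes, TGF-beta targets, CIMP panel genes and small RNA pathway.

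Markers of cell types that a culture of this line should not hold were mostly dim. Median control signals were 9.38 for fibroblast, 7.18 for endothelial, 9.35 for lymphocyte, 9.15 for myeloid and 9.45 for hepatocyte markers, all below the array medians, and 31.2 for neuronal markers. Some neuronal markers were bright: 6 of 10 lay above the filter, and the highest control signal was 2085 (TUBB3, named after its value was seen). Of the markers, 1 fibroblast gene (COL1A1, 0.47), 1 endothelial gene (ESAM, 1.45) and 1 neuronal gene (SYT1, 0.57) rose; COL1A1 and SYT1 were named after their values were seen. With the mean of all its probe sets COL1A1 was at -0.073 (adjusted p = 0.817). The neuronal list did not pass (camera adjusted p = 0.154 as the only marker list tested), and the others had under 5 genes above the filter and were not tested. The ratio of 3' to 5' probe set signals, a sign of RNA integrity, was 0.858 and 0.846 for GAPDH with control siRNA and 0.884 and 0.858 with TET1 siRNA. For beta-actin it was 1.21 and 1.19 against 1.28 and 1.26.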

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

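Probe sets that the annotation used here ties to no gene symbol, or to several, entered no gene-level comparison, and they hold signals that differ between the groups. Among 2834 probe sets with no gene symbol above the filter, 250 passed when each probe set was tested by itself with limma (113 higher and 137 lower after TET1 siRNA, 8.82%). Among 1120 probe sets with several gene symbols, 190 passed (98 higher and 92 lower, 17.0%). The share among probe sets with 1 gene symbol was 16.9% (3947 of 23352). No biological explanation was tested for these probe sets.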

How the results depend on the processing

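The alternatives were fixed before the data were examined. The TET1 transcript was lower and past the threshold in all 13 moderated alternatives in which it was followed. Its log2 difference ran from -1.92 (pseudocount 1) to -0.64 (pseudocount 64), with limma adjusted p from 7.88e-04 to 0.017. It was -1.30 to -1.27 when 1 array was left out. TET1 lies below the upper-quartile filter, which gave no value. In limma without moderation it did not pass, and no other gene did. Leaving out 1 array gave 813 to 1157 genes higher and 879 to 983 lower, and 9 to 10 lists, from a fit in which the lone array is assumed to vary like the other group. Without TET1 siRNA replicate 1 it was 813 and without TET1 siRNA replicate 2 835 genes higher. Counts of genes higher and lower were 437 and 535 without a variance trend, 899 and 847 with no filter, and 425 and 532 at 1.5-fold or more. They were 57 and 127 at 2-fold with no test, 0 and 0 in limma without moderation (2671 genes at unadjusted p below 0.05, lowest adjusted p 0.0898), and 2119 and 2268 with each probe set tested by itself. They were 772 and 892 with the mean of all probe sets, and 882 and 908 without _x_at and _s_at probe sets. With an estimated correlation 0 lists passed, and 3 had unadjusted p below 0.05, among them oxidative phosphorylation and autophagy and lysosome. Fry called 7. Fewer genes pass without moderation because 2 residual degrees of freedom remain, and camera with an estimated correlation rests on the same 2. Oxidative phosphorylation (estimated correlation -2.33e-04), autophagy and lysosome (-0.0065) and NRF2 targets (-0.039) lost their calls with estimates below the preset 0.01. The estimate was above it for replication-dependent histones (0.496), S phase (0.373), YAP targets (0.177), G2/M and mitosis (0.138) and hypoxia response (0.039). For these lists correlation and the few degrees of freedom were not told apart. The cause of the other changes was not tested.

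Same-numbered arrays did not deviate together (correlation of deviations 0.0058), and 2 pairs cannot show that the numbers pair the samples. With the replicate number as a block, 1442 genes were higher and 1348 lower, the TET1 log2 difference was -1.28, and 10 lists passed.

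Of 189 genes followed across the settings that passed, 183 did so after quantile normalization, 178 after median centring, 104 without a variance trend, 143 with no filter, and 145 to 161 without 1 array, with no change of sign. With the mean of all probe sets 120 of 189 passed, and without _x_at and _s_at probe sets 117 of 136. Signs of these genes changed only where other probe sets were used. Some of the 189 had been picked because their probe sets passed in opposite directions, which favours such changes. Among all calls 63 of 2687 changed sign with the mean of all probe sets, and 85 of 2053 without _x_at and _s_at probe sets. With the mean of all probe sets the log2 difference was -0.023 for ICAM1, -0.017 for ATF3, -0.23 for ADH5, -0.22 for AGPAT5, -0.11 for BCCIP, -0.46 for DLD, -0.13 for GSPT1, -0.27 for LRPAP1, -0.16 for MRPS30, -0.27 for MXRA7, -0.45 for NUDT5, -0.060 for SRRD, -0.093 for TIPRL, 0.13 for TMF1, 0.23 for VPS50, -0.085 for YIPF6 and -0.073 for COL1A1. Without _x_at and _s_at probe sets it was -0.047 for JUN, 0.014 for GINS2, -0.0029 for ATF3, -0.24 for APC, -0.054 for CFLAR, -0.73 for SQSTM1, -0.70 for ADH5, -0.75 for BCCIP, -0.41 for GSPT1, -0.43 for MXRA7, -1.33 for NUDT5, -0.51 for SRRD, -0.47 for TMEM30A and 0.43 for TMF1, and 0.42 for HNRNPD, which is not among the 189 (-0.22, adjusted p = 0.146, with 1 probe set per gene). These values come from, or include, other probe sets of the gene. Signal over background limits dim genes most: the filter lies at a signal of 13.1, near the array medians.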

Other observations

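Tests of RNA quality, of cross-hybridisation and of other splits of the arrays, and the scan of gene families, were chosen after the values they measure, or the list of genes they use, had been seen. Whether the tests of opposite probe sets decide anything was read from intervals only after their values had been seen; point values alone would have counted against both explanations. The bound for RNA quality was first 0.5 in the log2 ratio, under which it counted as excluded; it was replaced after the ratios had been seen, because that bound was tied to no shift of the list, and RNA quality is now read as open. In a scan beside the fixed lists, 217 families of genes that share the letters of their symbol and have 8 or more members were tested with camera. The metallothionein genes (MT) were lower: 5 of 8 fell and none rose, with a median log2 difference of -0.32 (MT1E -0.23, MT1F -0.32, MT1G -0.32, MT1HL1 -0.54 and MT2A -0.29). The NDUFA genes of respiratory complex I were higher (7 of 12 rose, none fell, median 0.21), and 6 of them are also in the oxidative phosphorylation list. So were the genes with MRPL symbols, which are genes of the mitochondrial ribosome but for 1 antisense gene (12 of 49 rose, median 0.14), of which MRPL20 (-0.56) and MRPL30 (-0.35) fell. Genes with MRPS symbols, also named for the mitochondrial ribosome, did not pass (4 of 27 rose and 3 fell, median 0.058, camera adjusted p = 0.971). MT, NDUFA and MRPL each had camera adjusted p = 0.0449, and with an estimated correlation the adjusted p was 0.972. The directions held under quantile normalization and median centring, but calls were lost. The adjusted p was 0.0144 for MT, 0.186 for NDUFA and 0.228 for MRPL after quantile normalization, and 0.0583 for each after median centring. Without _x_at and _s_at probe sets it was 0.574 for NDUFA and 0.715 for MRPL, and too few MT genes were left to test. Metallothionein genes are near-identical copies read by overlapping probe sets, so single values are uncertain. The tubulin genes TUBA1A and TUBB changed in opposite directions: TUBA1A rose from 2642.4 ± 96.1 to 5699.6 ± 179 and TUBB went from 4435.2 ± 25.8 to 2265 ± 6.79 (SD, n = 2; log2 differences 1.10 and -0.96). All genes of this paragraph were chosen after their values were seen.

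Among the 100 genes of lowest p, 71 were lower after TET1 siRNA (95% Wilson interval 61.5 to 79.0), while 51.5% of all calls were higher and 497 of the 1000 genes of lowest p were lower. The intervals treat genes as independent and leave out the spread between arrays, so the counts describe these arrays only. Quantile normalization, after which 74 were lower (64.6 to 81.6), argues against the differences between arrays that it removes as the whole cause. With each array centred on its median 65 were lower (55.3 to 73.6) and 59.0% of all calls were higher, so how much of the excess rests on a shift between arrays stays open. In the upper quartile of signal 70 were lower (60.4 to 78.1). On these arrays this argues against compression of rises that start near the background as the whole cause. Without control siRNA replicate 1 the number was 57, and without control siRNA replicate 2 it was 66. It was 76 without TET1 siRNA replicate 1 and 73 without TET1 siRNA replicate 2. The excess thus varied with the array left out, and why was not tested. A direct action of the siRNA on transcripts that match its sequence was not tested, and loss of TET1 stays open as a biological explanation.

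The fall of the G2/M and mitosis list was weighed against 3 technical explanations. After quantile normalization its median log2 difference was -0.53, which argues against array scaling, and with each array centred on its median it was -0.48. The larger of the differences between groups in the 3' to 5' log2 ratio was 0.0832 (beta-actin). Both TET1 siRNA arrays lay above both control siRNA arrays in the beta-actin ratio, and what such a difference does to these genes was not tested, so RNA quality stays open. Of 89 probe sets of the list above the filter, 80 (89.9%) were lower, which argues against the choice of 1 probe set per gene. Loss of TET1, a response to the siRNA other than through TET1, and the density of the cultures were not tested.

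In 30 of 786 genes with 2 or more probe sets past the threshold (3.82%), probe sets passed in opposite directions: ADH5, AGPAT5, APPBP2, BCCIP, DCAF7, DLD, FOXP2, GPRC5A, GSPT1, HNRNPD, LAMP2, LCORL, LRPAP1, LRRFIP1, METTL21A, MRPS30, MXRA7, NCS1, NUDT5, PPM1A, PPP4R2, SH3GLB1, SQSTM1, SRRD, TIPRL, TMEM30A, TMF1, VPS50, YIPF6 and ZMAT3. In NUDT5, 1 probe set had a log2 difference of 0.42 and the other -1.33. At adjusted p below 0.005 the share was 1.49% (4 of 268 genes, 95% Wilson interval 0.582 to 3.77), which leaves false calls open because the interval holds a fall of the share to under its predicted bound. Probe sets named _x_at or _s_at, which can read several transcripts, were among the called ones in 18 of the 30 genes and in 541 of 756 genes whose probe sets passed in 1 direction (odds ratio 0.597, 0.267 to 1.38, Fisher's exact test p = 0.216), which decides nothing on cross-hybridisation. A change of transcript isoform was not tested.

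The 4 arrays can be split into 2 and 2 in 3 ways, which is too few for a share under 0.05. The real split called 2706 genes and was 1 of 3 to call as many. The highest of the other splits called 0 genes with limma (116 and 111 genes at unadjusted p below 0.05). Each of those splits puts 1 control siRNA and 1 TET1 siRNA array in a group, so the siRNA difference adds to the spread within groups. Their counts are therefore no baseline for chance.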
